A study of Rattus norvegicus with 8 samples.

How the data were processed

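RNA from the medial thalamus of 8 rats was hybridised to 2-colour Agilent rat arrays, with the animal in Cy5 and a pool of all 8 animals in Cy3 on every array and no dye swap. Per the file headers, the authors scanned the arrays and extracted them with Agilent Feature Extraction 9.5.1.1. The deposited scanner files give spot intensity on a linear scale (mean signal and median local background in each channel), together with a log10 ratio of Cy5 over Cy3 that the software computed from its own processed signals. The series' deposited value table holds the same log10 ratios, rounded. All 45018 spots of each array matched within 1%, so scale and direction were settled by this comparison. Each column's median was 0, but 7346 to 9980 values per column were exactly 0, so that median does not show how the ratios are centred. The direction of every ratio follows from the dyes named in the labels.

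Each array held 43379 spots outside controls, for 41012 probes. Probes were named through a rat RefSeq gene table of the GRCr8 assembly, used for names only. Of the probes, 10735 matched by accession without its version, 1222 by gene ID, 5501 by current symbol and 3718 by synonym. The other 19836 kept the name given by the array design, and 21338 probes carried a symbol.

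Intensities were background-corrected by normexp with an offset of 50 and normalised by loess within each array, with control and outlier spots at weight 0. Outlier spots were then left out and the spots of a probe averaged. Probes well above background in Cy5 on at least 4 of the 8 arrays, whatever the group, were kept, and at least 2 values per group were required. A gene was represented by its probe with the highest mean intensity, and 20 of the named genes had several tested probes, of which 6 had probes of opposite sign. This left 26964 genes, 13600 of them with a symbol. The lowest correlation between any pair of arrays was -0.20 over these genes and -0.15 over all probes.

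Occlusion was compared with control in limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The 35 fixed gene lists were tested with camera at its preset correlation of 0.01, and also with an estimated correlation, with fry, and by exact permutation of each animal's list mean over all 70 assignments. List tests used the 26172 genes measured on all 8 arrays. A first run had instead filled missing values with the gene's mean and gave 4 lists past the threshold in place of 2. The change was made after that run had been seen, in order to test measured values only, and both counts are given. The groups, lists, panel, tests and most alternatives were fixed before the data were examined.

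Genes are named by a fixed rule. It takes up to 10 genes in each direction past the threshold, with open places given to the genes with a symbol, separated groups and the smallest unadjusted p. It adds a panel of 18 genes, and up to 2 members of each list with the smallest unadjusted p. Members of the region and choroid plexus lists given beyond these, and Bcl3, Ptgs2, Thbd, Tekt4 and Cfap126, were chosen after their values were seen.

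The fit was tested on simulated data with the spreads of the 26964 genes and 200 changed genes in each of 5 runs. It recovered 56.0%, 84.4%, 93.2% and 97.2% of genes changed 1.5-fold, 2.0-fold, 3.0-fold and 4.0-fold, with 34 false calls among 861. Each simulated gene was drawn independently of the others. Alternatives covered background correction, normalisation, the deposited values, the filter on dim probes, several probes of a gene, array weights, slide and replicate number as blocks, each slide alone and each animal left out. Further fits without control 3 were added after it was seen to stand apart. Figures were drawn with matplotlib 3.10.9.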

Results

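Gene expression was measured in the medial thalamus of 8 urethane-anaesthetised Sprague-Dawley rats fitted with an inflatable cuff around the trachea. In 4 rats the cuff was inflated for 2 to 4 breaths at a time, followed by at least 15 breaths of recovery, and this was repeated for 10 min, after which the brain was removed at once. In 4 surgical controls the cuff was never inflated, and the brain was removed 70 min after setup. The time from setup to removal in the occluded rats is not given in the sources used here, so time under anaesthesia could not be compared between the groups and is not separable from treatment. Each animal was hybridised in Cy5 on 1 whole-genome rat oligonucleotide array against a pool of all 8 animals in Cy3, so every value is a log2 ratio of the animal to that pool. The arrays lay on 2 slides, each with 2 occlusion and 2 control animals. Median Cy5 signal over background ranged from 3.65 to 4.67, and between 68.3% and 80.2% of spots were well above background in Cy5. With 4 animals per group, the precision of these values is limited.

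The comparison of occluded with control rats asks which thalamic transcripts differ after brief repeated obstruction of breathing. Of 26964 genes tested, 0 passed an adjusted p under 0.05 (limma, Benjamini-Hochberg), with 0 higher and 0 lower, and the smallest adjusted p was 0.974. At an unadjusted p under 0.05 there were 842 genes, 494 higher and 348 lower, where chance alone gives 1348. That direction depended on scaling, with 222 higher and 60 lower after median centring and 368 higher and 584 lower on the ratios of the scanner software. Without control 3, whose region markers set it apart, 1 gene passed, Bcl3, and 1137 had an unadjusted p under 0.05, and that count was 489 without occlusion 1 and 1440 without control 1. The median absolute log2 difference over all genes was 0.07, with a median standard error of 0.10. In values simulated with these genes' own spreads, 56.0% of genes changed 1.5-fold and 84.4% of those changed 2.0-fold were recovered in the same fit. Each run held 200 genes changed 1.5-fold to 4.0-fold, drawn independently, which makes the adjusted threshold easier to pass than if few genes change. These shares are therefore not the power of the comparison where few genes differ. In the measured values 31 genes differed by at least 1 log2 unit and 0 passed.

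The genes with separated groups and the smallest unadjusted p, given as values and not as changes, were mostly small differences. Tnfrsf1a, the type 1 receptor for tumour necrosis factor, had a log2 ratio of 0.15 ± 0.05 (SD, n = 4) under occlusion and -0.28 ± 0.11 (SD, n = 4) in controls. Among the other 9 higher genes, Spmip6, Rsph9, Pierce2 and Dnai7 encode parts of motile cilia or flagella, with log2 differences of 0.50, 0.37, 0.36 and 0.51. Tmod3, which caps actin filaments, differed by 0.42, the folding enzyme Pdia4 by 0.33, Adap2 by 0.52, the DNA polymerase gene Polm by 0.30 and the endothelial matrix gene Mmrn2 by 0.29. Dimmer second probes gave smaller differences: 0.21 for Tmod3, 0.23 for Adap2, 0.02 for Mmrn2 and 0.35 for Dnai7. On the lower side, Dusp19, a phosphatase gene, differed by -0.54 with a standard error of 0.10, Cnot9 by -0.57, Nell2 by -0.50 and Clstn1, a synaptic calsyntenin, by -0.48. Arpc2, a subunit of the actin-branching complex, differed by -0.37, Tmem97 by -0.32, Celf2 by -0.23, Xylt1 by -0.23, Or6c35d by -0.21 and Eif1ad by -0.19. Dnai7 was measured in 3 controls. All 20 had an exact permutation p of 0.029, the smallest that 4 against 4 animals allow, and complete separation of the groups is what selected them. Over all tested genes, 684 had separated groups, where chance gives 2.86%, or 770 genes.

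**Figure D1:**
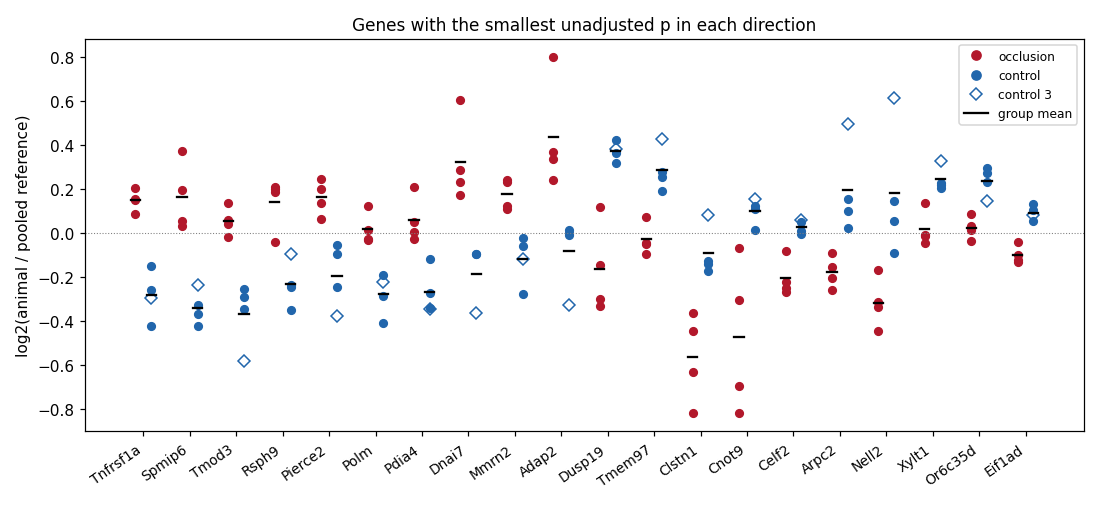
Log2 ratio of each animal to the pooled reference (vertical axis) for the 10 genes with the smallest unadjusted p in each direction among genes with a symbol and separated groups. Points are animals, bars are group means, and the open diamond is control 3.

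Genes induced by neuronal activity did not pass the test. Brains of occluded rats were removed at once after the 10 min protocol. Changes that develop later were thus not covered, here or for the hypoxia and stress lists below. Of 46 tested members of the immediate early gene list, 19 were higher and 27 lower under occlusion, with a median log2 difference of -0.04 (camera adjusted p = 0.359). Egr1, an activity-induced transcription factor, had a log2 ratio of -0.19 ± 0.34 (SD, n = 4) under occlusion and 0.29 ± 0.38 (SD, n = 4) in controls, with an exact permutation p of 0.143. Junb differed by -0.27, Gadd45b by -0.33, Egr4 by -0.80, Nr4a3 by -0.35, Arc by -0.32, Nr4a1 by -0.31, Dusp1 by -0.09, Fosb by -0.05 and Ier2 by -0.03, while Fos differed by 0.12. Of 18 genes in the fixed panel, 14 could be tested and 0 passed, either over all genes or adjusted over the list alone, where the smallest adjusted p was 0.468. The stress peptide gene Crh differed by -0.49, the glucocorticoid target Fkbp5 by 0.11, the angiogenic factor Vegfa by -0.02 and the serotonin receptor gene Htr2a, measured in 3 controls, by -0.01. Htr1a, Egr2 and Npas4 were well above background on 2, 1 and 0 arrays and were not tested, and Hspa1b was not matched to a probe. Control 3 carried much of the spread of the controls, with Fos at -1.74, Arc at 1.56 and Egr4 at 1.92. Without it the log2 difference of Fos was -0.34, of Arc 0.20, of Nr4a1 0.08, of Ier2 0.03, of Htr2a 0.41 and of Vegfa 0.07, so these 6 of the 14 panel genes changed sign. Egr4 moved to -0.21, Egr1 to -0.30 and Nr4a3 to -0.03, and the median of the immediate early gene list turned to 0.006.

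**Figure D2:**
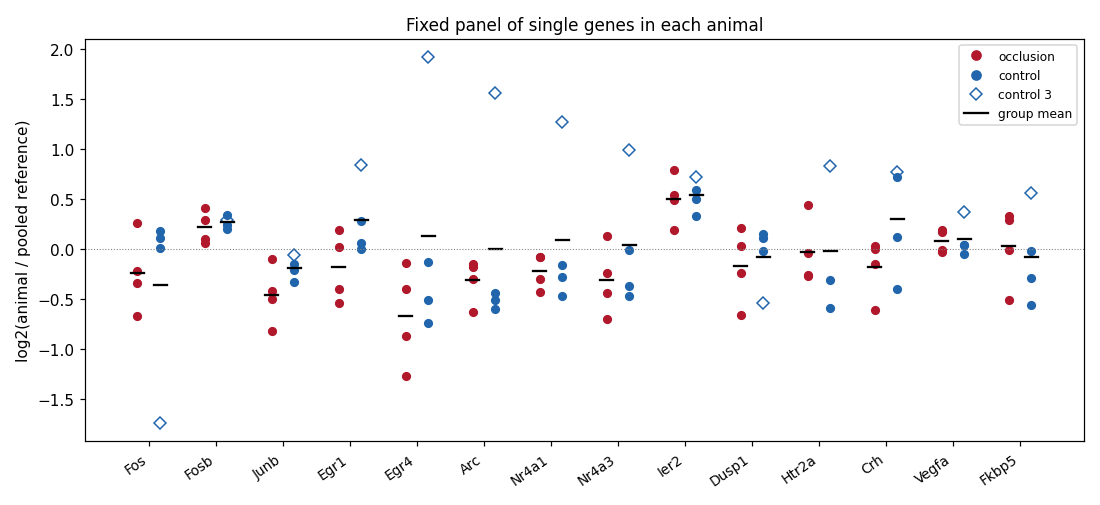
Log2 ratio of each animal to the pooled reference (vertical axis) for the panel genes that could be tested. Points are animals, bars are group means, and the open diamond is control 3, which lies apart from the other controls for Fos, Egr4, Arc and Nr4a1.

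Inflammation genes were shifted upwards as a list. Of 26 members, 18 were higher and 8 lower, with a median log2 difference of 0.08 (camera adjusted p = 0.0255), but the call did not hold with an estimated correlation (adjusted p = 0.590). Vcam1, an endothelial adhesion molecule, differed by 0.29 and the iron-binding protein gene Lcn2 by 0.23, and 0 members passed either over all genes or adjusted over the list alone. List means lay between 0.02 and 0.11 in the occluded rats, and were -0.19, -0.13 and -0.13 in controls 1, 2 and 4 but 0.17 in control 3, giving an exact permutation p of 0.200. Without control 3 the median was 0.13 (camera adjusted p = 1.6e-06), with an adjusted p of 0.0594 under an estimated correlation. The exact permutation p was then 0.0286, the smallest possible, and was not adjusted over the lists. Control 3 lay above every occluded rat on this list, so leaving it out removed the animal that opposed the shift. The p-values without control 3 therefore cannot be read as evidence of a shift. Meningeal and fibroblast markers were also higher without control 3 (0.22, camera adjusted p = 0.00277, but 0.569 with an estimated correlation). The inflammation call was lost without control 1 (median 0.083, adjusted p = 0.0668) or without control 2 (0.065, 0.0872), within slide 1 (0.053, 0.267), on Cy5 alone (0.064, 0.0603) and with probes well above background on all arrays (0.066, 0.0681). With slide as a block it passed. It also passed within slide 2, where the meningeal (0.287), pericyte (0.157) and endothelial (0.117) lists were higher too, while within slide 1, where control 3 is 1 of 2 controls, the meningeal (-0.684) and pericyte (-0.257) lists were lower.

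Choroid plexus and ependyma markers were the other list shifted upwards. Of 16 members, 13 were higher and 3 lower, with a median log2 difference of 0.51 (camera adjusted p = 0.00279, against an adjusted p of 0.590 with an estimated correlation). Clic6 differed by 0.66, Tekt1, a ciliary tektin, by 0.54, and 0 members passed over all genes or adjusted over the list alone. The list mean was -0.06, -0.16, 0.50 and -0.46 in occlusion 1 to 4 and -0.28, -0.50, -0.97 and -0.52 in control 1 to 4, with an exact permutation p of 0.0571. Occlusion 3 and control 3 lie at opposite ends, and the median was 0.313 without control 3, 0.248 without occlusion 3 and 0.19 within slide 2. On the ratios of the scanner software it was 0.827, and the inflammation median there was 0.148. Ttr, an abundant transcript of choroid plexus, was 2.28 in occlusion 3 and between -2.79 and -1.76 in the other 7 animals.

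Region markers did not pass between the groups but set control 3 apart from every other animal. The mean of 16 thalamic relay neuron markers was -1.70 in control 3 and between -0.37 and 0.20 in the other 7 animals. The mean of 13 cortex markers, 10 of them above background on all 7 other arrays and 3 of them on another list, was 1.17 in control 3 and between -0.76 and -0.28 in the others. Slc17a6, the vesicular glutamate transporter of thalamic projection neurons, was -2.99 in control 3, and Prkcd was -3.01, whereas Neurod2, a cortical transcription factor, was 2.60 and Nrgn 1.66. Meningeal and fibroblast markers were also high in control 3, at 1.09, against 0.08 or below elsewhere. As group differences, thalamic relay markers had a median of 0.29 (adjusted p = 0.0951), cortex markers -0.31 (0.166) and meningeal markers -0.17 (0.243), all by camera. Without control 3 the medians became -0.13, 0.11 and 0.22, with adjusted p of 0.00755, 0.108 and 0.00277, so all 3 turned their direction, and none passed with an estimated correlation.

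**Figure D3:**
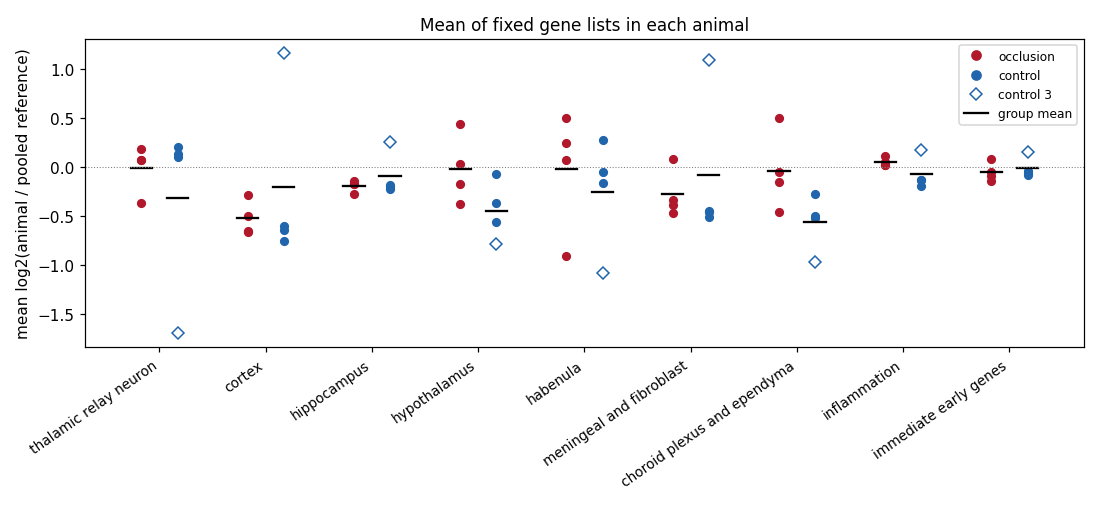
Mean log2 ratio to the pooled reference over the members of 9 fixed gene lists (vertical axis) in each animal. Points are animals, bars are group means, and the open diamond is control 3, at -1.70 for thalamic relay neuron markers and 1.17 for cortex markers.

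The remaining lists did not pass in the main fit. The hypoxia list, with 38 members, had a median log2 difference of 0.01 (camera adjusted p = 1), with Slc2a1 at 0.26 and Pdk1 at -0.30. Medians for stress-related lists were 0.03 for the glucocorticoid response (0.325), 0.04 for heat shock and unfolded proteins (0.0951), 0.08 for oxidative stress (0.0533) and 0.04 for apoptosis (0.331), with adjusted p in brackets. In the transmitter lists the medians were 0.02 for serotonin (0.331), -0.04 for dopamine and noradrenaline (0.331), 0.10 for GABA (0.169), -0.10 for glutamate (0.169), 0.05 for acetylcholine (0.397) and 0.04 for neuropeptides (0.155). Abat, which degrades GABA, differed by 0.39, Gabra3 by 0.30 and Cartpt, a hypothalamic peptide gene, by 1.96 with a standard error of 0.87. Occlusion 1 carried much of the Cartpt value, at 2.75 against -1.37, -0.90 and -0.81 in occlusion 2 to 4, and without it the difference was 1.01. Ion channels had a median of -0.05 (0.200), oxidative phosphorylation 0.01 (0.568), glycolysis 0.01 (1) and cytosolic ribosomal proteins -0.05 (0.0533), with 45 of 66 ribosomal members lower. The ribosomal list passed, lower, with slide as a block (camera adjusted p = 0.0391). By camera at its preset correlation it passed, lower, in 14 of 31 alternatives. Without control 3, whose ribosomal mean was 0.23, the ribosomal median turned to 0.02, that of acetylcholine to -0.11 and that of heat shock and unfolded proteins to -0.0004. Other medians kept their sign but moved in size. They became 0.12 for the glucocorticoid response, 0.03 for oxidative stress, 0.04 for GABA, -0.03 for glutamate, -0.0009 for dopamine and noradrenaline, and 0.11 for neuropeptides.

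Cell type lists gave medians of 0.13 for astrocytes (0.0533), 0.04 for oligodendrocytes (0.384), 0.13 for oligodendrocyte precursors (0.0951), 0.04 for microglia and macrophages (0.384) and -0.02 for neurons in general (0.837). Sox9, an astrocyte transcription factor, differed by 0.56 and Pdgfra, a precursor marker, by 0.24. The next brightest Sox9 probe gave 0.49, while its dimmer probes gave -0.04 and 0.02 and so differed in sign. Vessel lists had medians of 0.03 for endothelium (0.384) and -0.03 for pericytes and smooth muscle (0.743), and blood lists -0.07 for red cells (0.196) and 0.09 for neutrophils (0.331). Neighbouring regions gave 0.01 for hippocampus (0.904), 0.11 for hypothalamus (0.0951), 0.25 for habenula (0.342), 0.01 for reticular and inhibitory neurons (0.397) and -0.04 for striatum (0.539). Without control 3 the habenula median was -0.06 and that of reticular and inhibitory neurons 0.53, and oligodendrocytes turned to -0.01 and pericytes and smooth muscle to 0.01. Astrocytes fell to 0.07, oligodendrocyte precursors to 0.06 and hypothalamus to 0.03, while red cells moved to -0.15. In all, 10 of the 35 list medians changed sign without control 3. The median and the mean differ in sign for the hypoxia, glycolysis, neuronal and hippocampus lists. Of the 35 lists, 2 passed by camera with its preset correlation of 0.01, and 0 passed with an estimated correlation, by fry, or by exact permutation of list means after adjustment. The camera count ranged from 3 to 10 with each animal left out. Without control 3 it was 7, which added higher neuropeptides (adjusted p = 0.00453), glucocorticoid response (0.00755), reticular and inhibitory neurons (0.00277) and meningeal markers (0.00277), and lower thalamic relay markers (0.00755), and with an estimated correlation 0 passed.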

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

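The tests of control 3, and that of occlusion 3 alone, were chosen after those values had been seen. There were 142 checks, each of 1 list, gene or array measure within 1 of the 2 groups of 4 animals. In 14 of them 1 animal lay far from the other 3, relative to the range of the 4 values, and control 3 was that animal in 8. Independent checks would give about 1 in 20, or 7.1. These checks share animals and genes, so 7.1 is no test of chance and the 8 are not separate observations.

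Control 3 lay at -1.70 for thalamic relay neuron markers, 1.17 for cortex markers, 0.26 for hippocampus markers, 1.09 for meningeal and fibroblast markers and -0.48 for cholinergic signalling, as well as at -1.74 for Fos, 1.56 for Arc and -0.33 for Adap2. A poor array is argued against only weakly. Control 3 was the worst of the 8 arrays on 0 of 3 quality measures (spike-in correlation 0.994, 80.2% of Cy5 spots well above background, 212 outlier spots). Only controls 1 and 2 were the worst on any of these, so most arrays would meet this criterion. Control 3 also had the largest SD of log2 ratios, 0.42, and the lowest median correlation with the other arrays, -0.12. RNA that never entered the pool is argued against too. Over cortex markers the ratios of the 8 arrays averaged 0.975, close to the value that a pool containing this animal's RNA must give, though RNA mislabelled before pooling would also give it. Cortical and meningeal tissue in the piece labelled control 3 remains a candidate explanation that was not tested independently: the smaller of its gaps to the nearest animal on the cortex and relay lists, 2.33 times the range of the other 7, only restates what set it apart. Foxp2 and Lhx2, each on 1 of these lists but not specific to it, moved against their list. No biological explanation was tested, as the labels describe this rat like the other controls.

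The higher choroid plexus and ependyma markers under occlusion remain open among chance, the treatment and the makeup of the dissected pieces. By exact permutation of list means p was 0.0571, and 0.833 after adjustment over the lists. Without control 3 the list's median log2 difference was 0.313, above the bound of 0.25 set for a single animal as the source. Without occlusion 3 it was 0.248, below that bound. By the bound alone control 3 would not be the only source, while occlusion 3 could be. Each value lay within 1 standard error (0.22 and 0.19) of the bound, an allowance made after these values were seen, which leaves both undecided. That standard error is of the group difference in the animals' list means, not of the median. Uneven amounts of ventricle lining may also account for the higher list: without control 3 the members' deviations had a mean pairwise correlation of 0.264, between the bounds set for and against. Uneven lining cannot be told apart from an effect of occlusion here, because the amount of lining in each piece is known only from these same transcripts.

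Other values far from their group, relative to its range and not always in size, were -0.0488 for the oxidative stress list and -0.0390 for Rsph9 in occlusion 4. That oxidative stress value lay within the controls, which ran from -0.22 to 0.02. The red blood cell list was -0.51 in occlusion 1. Control 1 had the endothelial list at -0.13, 68.3% of Cy5 spots well above background and 853 outlier spots. Occlusion 1 also had the endothelial list at -0.13.

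For the 842 genes at an unadjusted p under 0.05 chance could not be excluded: 21 of the 35 splits into 4 and 4 gave as many, and the highest other count, 1908, came from the split that follows the 2 slides. With slide as a block the count was 893, and it was 1071 within slide 1 and 753 within slide 2. Nor could it be excluded for the 2 gene lists, as 35 splits gave as many, up to 13. For the 0 genes at adjusted p under 0.05 and the 0 panel genes the splits decide nothing, because all 35 must reach a count of 0; the highest other values were 0 and 1.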

How the results depend on the processing

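The fits without control 3 with a second change, and that with missing values filled, were chosen after the data had been seen. The number of genes past the threshold stayed at 0 in 32 of 33 alternatives and was 1 without control 3, a range of 0 to 1 with each animal left out. A 1.5-fold minimum on top of 0 genes could only give 0. In every count of alternatives here, the deposited values repeat the scanner software's ratios and are not a separate check. The panel gave 0 genes in all 30. The count at an unadjusted p under 0.05 was within 1.5 times of 842 in 26 of 31 alternatives. It was 282 with median centring, 1335 with array weights, 287 with median centring and no control 3, and 489 to 1440 with each animal left out (occlusion 1 and control 1). The count of lists, 2, moved most: 4 without background subtraction, 13 with median centring, 1 with probes well above background on all arrays, 4 with the mean over probes, 11 within slide 1, 8 within slide 2, and 3 to 10 with each animal left out. It was 3 with slide as a block, adding ribosomal proteins, and 4 with missing values filled, adding astrocyte markers and ribosomal proteins. With an estimated correlation, with fry and with exact permutation it was 0. Without control 3 it was 9 with a slide block, 6 on Cy5 alone, 11 with median centring and 8 without occlusion 1 too. Choroid plexus and ependyma markers passed in 31 of 31 alternatives by camera at its preset correlation and inflammation in 26, and neither passed with an estimated correlation (0.590 each). The cause of these shifts was not tested. After each group's mean was subtracted, same-numbered animals, which share a number and an array position, correlated at -0.13, 0.14, 0.02 and 0.08. Of the 8 animals, only control 2 correlated best with its own number. With a replicate block, which is also a block of array position, 0 genes, 811 unadjusted genes and 10 lists passed, and 10 lists with slide and replicate block. Aquantile scaling leaves log ratios as they are and so tests nothing here. Signal over background of 3.65 to 4.67 limits dim genes.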

Other observations

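Without control 3, 1 gene passed, and the tests of it below were set before they were run, after the gene had been seen. Bcl3, a nuclear regulator of NF-kappaB target genes, had a log2 ratio of 0.34 ± 0.12 (SD, n = 4) under occlusion and -0.77 ± 0.13 (SD, n = 3) in controls 1, 2 and 4, a difference of 1.104 with a standard error of 0.09 (limma adjusted p = 0.0346). Control 3 lay at 0.20, and with it the difference was 0.86 (adjusted p = 0.974). By unadjusted p the next genes were Ptgs2, the inducible cyclooxygenase, at 0.55 (adjusted p = 0.355) and Thbd, the endothelial thrombomodulin, at 0.82 (0.917), then the ciliary genes Tekt4 at 0.45, Cfap126 at 0.68 and Spmip6 at 0.54 (each 0.917), and none of these passed. With all 8 animals the differences were 0.21 for Ptgs2, 0.52 for Thbd, 0.67 for Tekt4, 1.11 for Cfap126 and 0.50 for Spmip6.

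An inflammatory response to occlusion is at most a hypothesis from these values. With all 8 animals the inflammation list had an exact permutation p of 0.200, and a camera adjusted p of 0.590 with an estimated correlation. Meningeal and fibroblast markers were also higher without control 3, by 0.22, if only at the preset correlation of camera (adjusted p = 0.569 with an estimated one). Control 3 was the highest animal on that list, at 1.09, and with all 8 animals its median difference was -0.17. Of the 35 splits of the 7 animals, 1 gave as many genes, the real one, against 0 in the highest other. That count says nothing about chance here: among the 8 fits that leave out 1 animal this one was taken up because a gene passed in it, and the animal it leaves out lay within the range of the occluded rats for Bcl3, 0.18 to 0.45. The call may rest on the number of animals: leaving out 1 more animal, Bcl3 passed in 0 of 7 fits, with a difference between 1.04 and 1.17 and an adjusted p between 0.0586 and 0.496. It also passed in 0 of 4 fits without control 3 that changed the block or the normalisation. There the difference was 1.08 with slide as a block and 1.198 on the ratios of the scanner software. On Cy5 alone it was 1.17, and with median centring 1.21. All of these fits leave out control 3, so they do not bear on the difference of 0.86 with it.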
